A study of Mus musculus with 2 samples.

How the data were processed

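RNA from the polysome fractions of sucrose gradients was measured in 2 samples of 1 group, wild-type male FVB mouse brain on postnatal day 25 without the major white matter tracts. Per the labels, RNA was extracted with Trizol, depleted of ribosomal RNA with the RiboMinus kit and labelled with the Affymetrix WT Sense Target assay. The labels name the molecule as total RNA and its source as polysome fractions. Per the series' design text, polysomes were prepared in duplicate from 2 mice and RNA was taken from each gradient. That each sample is exactly 1 mouse is not spelled out there.

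The deposited values are array intensity on a linear scale, 1 per transcript cluster and sample. Affymetrix Power Tools, PLIER (a method that summarises probe intensities) and the mouse build mm8 are named per the submitters' processing notes, without versions or roles. The background correction and the scaling between the arrays are not given in the sources used here. The deposited intensities ran from under 0.001 to 11219 in sample 1 and 11994 in sample 2. Their medians over all clusters were 35.3 and 44.7, so the deposited values did not have equal medians. Values under 1 made up 5.81% and 3.07% of clusters, and 32 clusters had identical values in both samples. Near-zero values make log2 differences large at low signal.

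Genes were named from the platform annotation supplied with the table. Of 100843 clusters, 22608 had 1 symbol, 1462 several and 76773 none. Clusters with 1 symbol were used, and those with several or none were left out of the comparisons. The Entrez identifiers of 22101 single-symbol clusters (97.8%) were in a RefSeq gene table of assembly GRCm38.p6, used for names and synonyms only, and 0 symbols differed. A gene's value was the median log2 intensity of its clusters, 1 cluster for 17432 genes and more for 2179. No pseudocount was added.

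The control-gene level was the 95th percentile of the chemosensory receptor genes in each sample. Pearson and Spearman correlations and the SD of the log2 difference described how far the samples differed. Differences were log2 of sample 2 minus sample 1 after centring each sample on its median over genes, and a gene counted as 2-fold different if it was above the level in at least 1 sample. The 38 gene lists (cell types, tissues, pathways and controls) were described by counts above the level, counts in the top 10%, and the median percentile rank. For lists of at least 5 measured genes, the median difference was set against 10000 random lists matched on mean signal in 20 bins. A list outside the middle 95% of these was taken to stand apart, which is a description of these samples and not a p-value. Intervals of median ranks were 95% bootstrap intervals of 10000 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

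The lists, the comparisons, the rule for named genes and the alternative settings were fixed before the data were examined, except alternatives on centring. The rule named the 20 genes with the highest mean log2 signal and the 10 largest differences each way among genes at or above the median signal. For each list described it named the 4 brightest and 2 dimmest measured members by mean log2 signal and, in the difference, the 4 largest absolute differences among members above the level. It also named all measured members of the sex-linked, pituitary, blood and choroid plexus lists. Alternatives covered quantile normalization, the brightest cluster per gene, a pseudocount of 16, another control list, the 99th percentile of controls, genes at or above the median signal only, each sample alone, a 1.5-fold threshold, no matching, other centring, and counting clusters with several symbols. Correlations that moved by over 0.05 were counted as moved, a tolerance set here.

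The procedure was tested on simulated differences between the 2 samples for 19611 genes. At the 2-fold threshold it recovered, with the right sign, 96.5% of 4-fold differences planted in genes above the control-gene level in both samples. Genes above it in 1 sample only were given none, and the share of false 2-fold calls was not computed. A 16-gene list shifted by 0.85, the size and median difference of the immediate early list, was put at percentile 100. Of 200 unshifted 20-gene lists, 5.5% fell outside the middle 95%. These lists were drawn at random from genes given independent noise, so a share near that was set by construction. It does not give the share for real lists, whose members are related genes.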

Results

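The data were 2 exon array profiles of RNA from the polysome fractions of mouse brain, that is, RNA sedimenting with several ribosomes in a sucrose gradient. Both samples came from wild-type male FVB mice on postnatal day 25, from whole brain without the major white matter tracts, and formed 1 group with n = 2. The question was how abundant each mRNA was in these fractions. The deposited table held 100843 transcript clusters, the units for which the array gives a signal. Of these, 22608 had a single gene symbol and covered 19611 genes, 1462 had several symbols and 76773 had none. Median intensity over these genes was 81.0 in sample 1 and 110.3 in sample 2, a shift of 0.44 on the log2 scale. The number of arrays limits the precision. With 1 group no test between groups could be made, no p-value is given, and the spread between the samples may be partly technical.

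Most lists of neuronal and glial genes ranked high, monoamine neuron genes being an exception, and genes that brain mostly lacks ranked low. The median percentile rank of signal was 99.02 for pan-neuronal genes, 96.7 for astrocyte genes and 12.9 for chemosensory receptor genes. The reference was the 95th percentile of 954 odorant, vomeronasal and taste receptor genes, called the control-gene level, at an intensity of 104 in sample 1 and 96.5 in sample 2. In both samples, 8105 genes (41.3%) lay above it, as did 34 (3.56%) of the receptor genes themselves. Another 2883 genes lay above it in 1 sample only. Across all genes, which are not independent replicates, Pearson's r between the samples was 0.73 and Spearman's rho 0.92 on log2 intensity. Among genes above the level in both samples these were 0.91 and 0.88. The SD of the log2 difference between samples was 2.95 in the lowest tertile of signal, 0.68 in the middle and 0.49 in the highest. There were 2 stricter references, the 95th percentile of genes restricted to other tissues and the 99th percentile of the receptor genes. With the tissue-restricted genes 4675 genes lay above the level, and with the 99th percentile 5016.

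**Figure D1:**
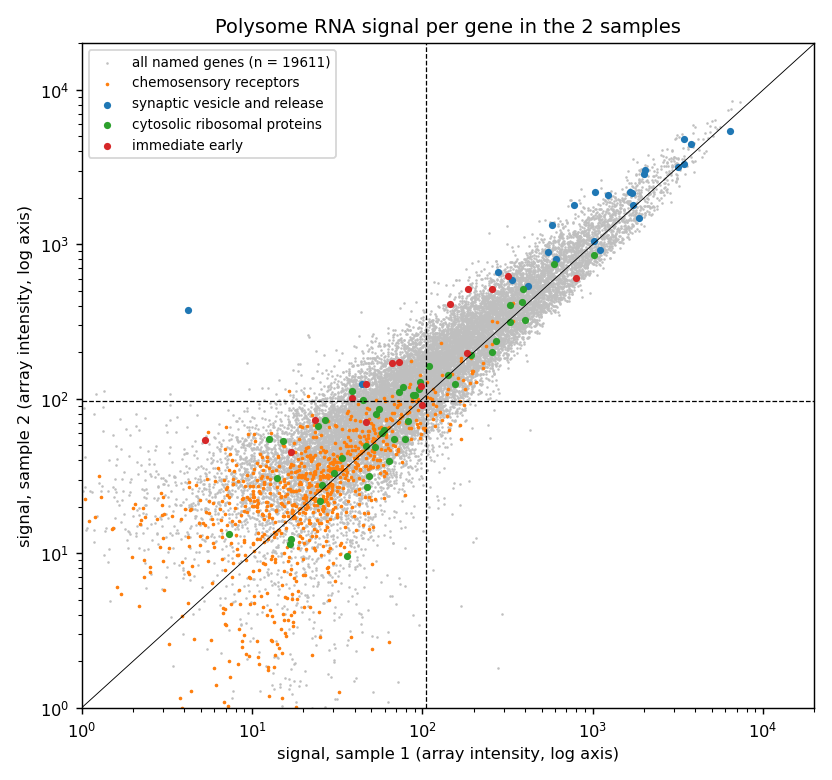
Intensity of each gene in sample 1 (x axis) and sample 2 (y axis), array intensity on log axes that start at 1, each small grey point a gene, with chemosensory receptor genes in orange and synaptic vesicle, cytosolic ribosomal protein and immediate early genes in blue, green and red. The solid line marks equal intensity and the dashed lines the control-gene level of each sample, above which the points narrow; 473 genes with a value under 1 in either sample lie outside the plot.

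The 20 named genes with the highest signal included genes of neurons, synapses, astrocytes and myelin. They were led by Atp1b1 at 7826 ± 729, Apoe at 7492 ± 1349.5, Faim2 at 7012 ± 712 and Cyfip2 at 6826 ± 883 (mean intensity ± SD, n = 2, as throughout). The SDs are of intensities without centring, so they also hold the log2 shift of 0.44 between the sample medians. A small SD can hide a centred difference, as for Syt1, at -0.44. List members are picked by mean log2 signal, so their mean intensities can be out of order. Atp1b1 encodes a sodium pump subunit, Apoe the lipid carrier made by astrocytes, and Cyfip2 a regulator of actin that binds FMRP. Next came the complexin gene Cplx1 at 5908 ± 712, the protein kinase A subunit gene Prkar1b at 5783 ± 791, Arf3 at 5656 ± 92.5 and the phosphatase subunit gene Ppp2r1a at 5647 ± 906. Ywhaz at 5477 ± 416, Aplp2 at 5453 ± 136, Nell2 at 5421 ± 1008 and Dpysl2 at 5369 ± 668 followed. The others were Cd81 at 5101 ± 334, Atp1b2 at 5052 ± 51.5, Slc22a17 at 4911 ± 459 and Camk2a at 4869 ± 1443, and Uchl1 at 4853 ± 1256, Mal at 4808 ± 54.5, Serinc1 at 4600.5 ± 272 and Rtn1 at 4566 ± 966. Mal encodes a myelin proteolipid and Camk2a a kinase of excitatory synapses. Signal depends on the affinity of each gene's probes as well as on RNA amount, so these values rank signals, not transcripts.

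Neuronal markers were among the highest signals of named genes. Of the pan-neuronal genes, 12 of 14 lay above the control-gene level in both samples and 10 in the top 10% of genes, with a median percentile rank of 99.02. The brightest were Uchl1 at 4853 ± 1256, Snap25 at 4141 ± 489, Gap43 at 3716 ± 364 and Syt1 at 3165 ± 1.39, and the dimmest Tubb3 at 167 ± 105 and Map2 at 25.7 ± 8.76. The value of Map2 was the median of 3 clusters. With the brightest cluster per gene, 13 of the 14 pan-neuronal genes lay above the level. For excitatory neurons 11 of 13 lay above the level (median rank 87.1), from Camk2a at 4869 ± 1443, Nrgn at 2667 ± 14.9, Slc17a7 at 1925 ± 319 and Grin2b at 1686 ± 348 down to Tbr1 at 62.5 ± 4.31 and Cux2 at 28.3 ± 5.49. For inhibitory neurons 12 of 14 did (median rank 92.5), led by Sst at 3434 ± 672, Cck at 2658 ± 812, Pvalb at 1502 ± 105 and Npy at 1493 ± 376, with Vip at 83.7 ± 4.06 and Htr3a at 82.5 ± 40.7 dimmest. All 11 measured cerebellar genes lay above it (median rank 97.8), including the granule cell gene Cbln3 at 3177 ± 537, the Purkinje cell genes Pcp4 at 2459.7 ± 722 and Pcp2 at 1824 ± 77.8, and Cbln1 at 1620.0 ± 320.2, with Zic1 at 683 ± 222 and Zic2 at 411 ± 105 dimmest. Striatal genes lay above it in 6 of 7 cases (median rank 96.2), among them the enkephalin gene Penk at 2892 ± 301 and Drd2 at 1463 ± 246, Pde10a at 1233 ± 356 and Ppp1r1b at 1141 ± 156, with Rgs9 at 629 ± 174 and Drd1 at 147 ± 62.5 dimmest. Monoamine neuron genes, which mark small nuclei, did so in 3 of 8 cases (median rank 36.3). They ran from Th at 225 ± 39.0, Slc18a2 at 185 ± 33.4, Slc6a4 at 163 ± 4.16 and Ddc at 96.5 ± 56.5 to Slc6a3 at 25.8 ± 14.1 and Tph2 at 14.0 ± 19.8, and 1 lay above the level with either stricter reference.

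Astrocyte and myelin genes were also widely detected. Of the astrocyte genes 10 of 12 lay above the control-gene level (median rank 96.7), led by Aldoc at 3309.7 ± 1081, Ntsr2 at 2457 ± 309, Slc4a4 at 1372 ± 282 and Gjb6 at 1326 ± 6.35, with Glul at 129.6 ± 83.8 and Aldh1l1 at 64.8 ± 24.4 dimmest. All 11 oligodendrocyte and myelin genes did (median rank 97.6), with Mal at 4808 ± 54.5, Cnp at 2603 ± 1116, Ugt8a at 1951 ± 342 and Mog at 1747 ± 260.0 brightest and Mbp at 425 ± 189 and Aspa at 346 ± 163 dimmest. Oligodendrocyte precursor genes did in 5 of 8 cases (median rank 70.8), from Olig1 at 1434 ± 283, Gpr17 at 975 ± 185, Sox10 at 407 ± 46.8 and Neu4 at 247 ± 8.71 to Bmp4 at 90.3 ± 11.97 and Cspg4 at 109 ± 92.5. Microglial genes did in 9 of 13 cases, none in the top 10% (median rank 75.3). The complement gene C1qb at 511 ± 89.3 led them, followed by P2ry12 at 508 ± 107, Csf1r at 479 ± 80.4 and C1qa at 463 ± 1.71, with Tyrobp at 80.2 ± 9.78 and Itgam at 56.8 ± 1.09 dimmest. Vascular genes were fewer above the level, at 3 of 10 for endothelium and 3 of 8 for mural cells. The brightest endothelial genes were Slc2a1 at 270.2 ± 39.9, Itm2a at 278 ± 123, Cldn5 at 108 ± 2.83 and Flt1 at 90.1 ± 41.2 and the dimmest Esam at 29.8 ± 1.59 and Slco1a4 at 19.5 ± 0.0601. The brightest mural genes were Rgs5 at 235 ± 52.2, Pdgfrb at 202 ± 44.6, Acta2 at 144 ± 49.4 and Tagln at 111 ± 54.9 and the dimmest Kcnj8 at 63.5 ± 8.45 and Myh11 at 67.5 ± 38.5. Meningeal and fibroblast genes lay above it in 7 of 10 cases, from Ptgds at 1749 ± 346, Igf2 at 777 ± 194, Slc13a4 at 424 ± 8.21 and Col1a1 at 293 ± 49.9 to Lum at 46.4 ± 23.1 and Col3a1 at 52.2 ± 49.4. With either stricter reference 1 endothelial and 0 mural genes lay above the level, and in sample 2 alone 6 mural and 8 precursor genes did.

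Choroid plexus and ependymal genes lay above the control-gene level in 4 of 11 cases (median rank 57.4). The thyroid hormone carrier gene Ttr was at 2989.6 ± 596, followed by Kl at 1062 ± 60.0, Sostdc1 at 169.6 ± 30.9 and Folr1 at 171 ± 72.3. The others were Otx2 at 149 ± 76.8, Foxj1 at 125 ± 40.0, Clic6 at 106 ± 49.7 and Kcne2 at 57.7 ± 27.8, and Aqp1 at 53.8 ± 55.6, Tmem212 at 32.7 ± 7.04 and Ccdc153 at 32.9 ± 16.7. In sample 2 alone 7 lay above the level, and with either stricter reference 2 did.

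Genes of pituitary, retina and blood, and interferon-stimulated genes, had no member above the control-gene level in both samples when measured by clusters of their own. Counting clusters shared with other symbols, 2 of 7 pituitary and 2 of 8 blood genes lay above it. The shared haemoglobin cluster of Hba-a1, Hba-a2 and Hbq1b, named after its values were seen, was at 133 ± 38.8. The 7 pituitary genes were Cga at 108 ± 18.4, Prl at 103 ± 18.7, Gh at 99.8 ± 55.2 and Tshb at 81.5 ± 6.12, and Pomc at 78.1 ± 29.97, Fshb at 71.9 ± 13.4 and Lhb at 50.9 ± 19.8. The 6 blood genes measured by clusters of their own were Ppbp at 94.0 ± 3.27, Alas2 at 81.2 ± 33.8 and Pf4 at 70.1 ± 13.5, and S100a9 at 34.5 ± 4.21, S100a8 at 23.5 ± 14.1 and Slc4a1 at 23.1 ± 24.4. Retinal genes ran from Rcvrn at 103 ± 15.3, Nrl at 96.5 ± 13.2, Pde6b at 84.8 ± 20.5 and Sag at 67.8 ± 27.5 to Crx at 20.3 ± 4.70 and Gnat1 at 13.9 ± 6.86. Interferon-stimulated genes, 13 in all (median rank 17.7), ran from Ifit2 at 87.2 ± 2.16, Usp18 at 88.5 ± 32.1, Ifi27 at 79.1 ± 40.7 and Bst2 at 57.4 ± 19.7 to Mx2 at 8.88 ± 6.73 and Isg15 at 3.27 ± 4.62. Of the sex-linked genes, none lay above the level in both samples, with the Y-linked Eif2s3y at 103 ± 49.4, Kdm5d at 88.7 ± 36.6 and Uty at 25.1 ± 21.0 and the X-linked Xist at 16.4 ± 5.33. In sample 2, Eif2s3y at 138 and Kdm5d at 115 lay above the level and Xist at 20.2 under it, while in sample 1 all 4 genes lay under it. Of genes typical of other tissues, 8 of 46 lay above the level (median rank 30.2), from Gast at 831 ± 134, Krt10 at 633 ± 115, Tnp2 at 205 ± 55.7 and Cela1 at 166 ± 30.6 to Csn2 at 3.21 ± 4.53 and Scgb1a1 at 2.39 ± 3.38. In sample 1 alone 3 pituitary genes lay above it, and in sample 2 alone 3 retinal, 1 blood and 13 tissue-restricted genes.

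**Figure D2:**
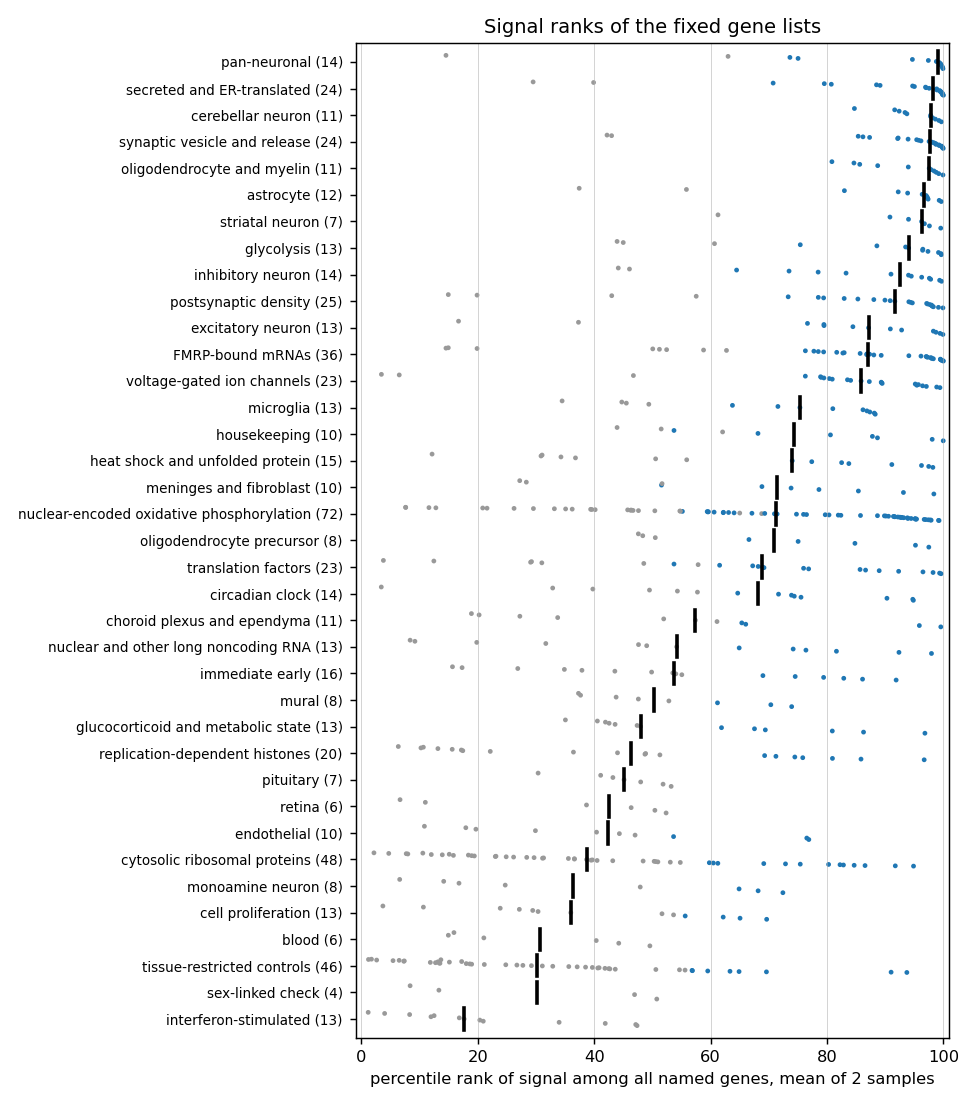
Percentile rank of mean signal among all genes (x axis, percent) for the members of each gene list (y axis), each point a gene, blue where it lay above the control-gene level in both samples and grey otherwise. Black bars mark medians and numbers in brackets the genes measured; pan-neuronal genes have a median rank of 99.02 and interferon-stimulated genes of 17.7.

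Genes of both sides of the synapse were widely detected in the polysome RNA. Of the synaptic vesicle and release genes, 22 of 24 lay above the control-gene level and 19 in the top 10% (median rank 97.7), led by Cplx1 at 5908 ± 712, Snap25 at 4141 ± 489, Dnm1 at 4134 ± 992 and Napb at 3359.8 ± 88.4, with Syn3 at 84.3 ± 56.6 and Syt11 at 189 ± 262 dimmest. Of the postsynaptic density genes 21 of 25 lay above it (median rank 91.6), including Camk2a at 4869 ± 1443, Gria1 at 2292 ± 477, Grin2b at 1686 ± 348 and Homer1 at 1593 ± 109.7, while the scaffold gene Dlg4 at 24.7 ± 4.85 and the receptor gene Grm5 at 32.8 ± 4.62 were dimmest. Voltage-gated channel genes lay above it in 20 of 23 cases (median rank 85.8), led by Scn2b at 2667 ± 396, Kcna1 at 1970.1 ± 98.4, Kcna2 at 1294 ± 290.1 and Kcnma1 at 1189 ± 377, with Scn3a at 13.0 ± 1.39 and Cacna2d1 at 7.32 ± 1.94 dimmest. FMRP is the RNA-binding protein lost in fragile X syndrome, and it associates with polysomes. Of a list of mRNAs known to be bound by it, 28 of 36 lay above the level and 15 in the top 10% (median rank 87.1). Its brightest members were Cyfip2 at 6826 ± 883, Camk2a at 4869 ± 1443, Map1b at 3421 ± 989 and App at 3032 ± 434, and its dimmest Map2 at 25.7 ± 8.76 and Dlg4 at 24.7 ± 4.85. That list was compiled from general knowledge of FMRP in brain, some of which may come from work on related samples, so it is not independent evidence.

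mRNAs of secreted proteins and of glycolysis ranked high, and those of oxidative phosphorylation were spread more widely. Secreted and endoplasmic reticulum-translated products lay above the control-gene level in 22 of 24 cases (median rank 98.2), led by Apoe at 7492 ± 1349.5, Itm2b at 4245 ± 1299, Sparcl1 at 3944 ± 431 and Itm2c at 3989 ± 1294, with Vgf at 72.0 ± 35.7 and Hapln1 at 47.9 ± 12.4 dimmest. Glycolytic genes did in 10 of 13 cases (median rank 94.0), from Aldoc at 3309.7 ± 1081, Eno2 at 3059.8 ± 647, Aldoa at 2252 ± 16.7 and Hk1 at 1391 ± 418 to Ldha at 80.9 ± 0.411 and Pgk1 at 78.3 ± 4.56. Nuclear-encoded oxidative phosphorylation genes did in 48 of 72 cases (median rank 71.2), from Atp5g3 at 2441 ± 377, Atp5b at 2258 ± 178, Ndufa12 at 1527 ± 113 and Uqcrc1 at 1500.3 ± 369 to Cox7b2 at 15.5 ± 8.11 and Cox8a at 15.6 ± 15.2.

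Cytosolic ribosomal protein genes lay mostly under the control-gene level, with 13 of 48 above it in both samples and a median rank of 38.7. The brightest were Rplp0 at 937 ± 112, Rpl17 at 673 ± 109, Rpl8 at 453 ± 88.7 and Rpl7l1 at 404 ± 30.8, and the dimmest Rpl29 at 14.1 ± 19.1 and Rps23 at 3.07 ± 3.34. Counting clusters shared with other symbols gave 27 of 78. Translation factor genes lay above the level in 16 of 23 cases (median rank 68.9), led by the neuronal elongation factor gene Eef1a2 at 3134 ± 890.3 and Eif3b at 2528 ± 328, Pabpc1 at 1663 ± 253 and Eef2 at 1152 ± 86.6, with Eif4g2 at 21.8 ± 0.0890 and Eef1g at 8.08 ± 1.70 dimmest. Housekeeping genes did in 7 of 10 cases (median rank 74.4), from Ywhaz at 5477 ± 416, Actb at 1574 ± 187, Sdha at 548 ± 223 and Hprt at 535 ± 262 to Ppia at 102 ± 13.3 and Pgk1 at 78.3 ± 4.56. Gapdh, named here after its values were seen, was measured only by 3 clusters shared with its pseudogenes, at 64.7, 35.4 and 13.6. In sample 2 alone 21 ribosomal protein genes lay above the level, and with either stricter reference 9 translation factor genes did.

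Stimulus-dependent and regulatory groups had median ranks from 48.0 for glucocorticoid and metabolic state genes to 74.0 for heat shock genes. Immediate early genes, which neurons induce within minutes of activity, lay above the control-gene level in 6 of 16 cases (median rank 53.8), from Egr3 at 701 ± 139.9, Dusp1 at 471 ± 219, Dusp6 at 385 ± 182 and Arc at 349 ± 231 to Klf4 at 31.2 ± 20.2 and Atf3 at 29.6 ± 34.3. Heat shock and unfolded protein genes did in 8 of 15 cases (median rank 74.0), from Hsph1 at 1753 ± 668, Hsp90b1 at 1376 ± 152, Dnajb1 at 1152 ± 337 and Atf4 at 648 ± 83.9 to Hsp90aa1 at 50.7 ± 8.53 and Ddit3 at 22.7 ± 14.0. Hsp90aa1 was dimmer than Manf, at 50.4 ± 3.75, by mean log2 signal only. Circadian clock genes did in 8 of 14 cases (median rank 68.2), from Dbp at 923 ± 16.1, Bhlhe41 at 915 ± 62.8, Arntl at 594 ± 116 and Per3 at 253 ± 33.2 to Nr1d1 at 54.9 ± 17.5 and Cry2 at 8.34 ± 11.8. Glucocorticoid and metabolic state genes did in 6 of 13 cases (median rank 48.0), from Mt1 at 1272 ± 425, Fkbp5 at 461 ± 161, Cdkn1a at 337 ± 43.1 and Sgk1 at 197 ± 62.1 to Angptl4 at 72.1 ± 24.4 and Txnip at 62.3 ± 36.1. In sample 2 alone 11 immediate early and 10 glucocorticoid genes lay above the level, and with either stricter reference 3 of each and 4 clock genes did.

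Some noncoding RNAs gave signal in the polysome fractions. Signal in these fractions does not by itself show that an RNA was bound to ribosomes, and neither sample was a control for this. Of the nuclear and other long noncoding RNAs, 6 of 13 lay above the control-gene level (median rank 54.2), led by the nuclear RNA Malat1 at 1861 ± 1049 and Tug1 at 734 ± 231, Miat at 345 ± 15.4 and Gas5 at 261 ± 8.18, with Kcnq1ot1 at 17.9 ± 7.20 and Xist at 16.4 ± 5.33 dimmest. Replication-dependent histone genes did in 7 of 20 cases (median rank 46.4), from H2aw at 1197 ± 8.16, H1f1 at 459.6 ± 109, H1f3 at 333 ± 5.43 and H2bc18 at 269 ± 68.4 to H2bu2 at 16.3 ± 12.8 and H2ac8 at 11.9 ± 2.70. Proliferation genes did in 4 of 13 cases (median rank 36.0), from Mcm5 at 199 ± 24.2, Dcx at 174 ± 90.4, Aurkb at 149 ± 18.1 and Birc5 at 115 ± 3.78 to Rrm2 at 17.4 ± 9.23 and Cdk1 at 8.64 ± 12.2, and 0 did with either stricter reference. Counting clusters with several symbols, 20 of 62 histone genes lay above the level.

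Between the samples, 583 genes were at least 2-fold higher in sample 2 and 487 at least 2-fold higher in sample 1, of 10988 above the control-gene level in at least 1 sample. Differences are log2 of sample 2 minus sample 1, each sample centred on its median over all genes. Among genes at or above the median signal, the largest differences toward sample 2 were in Nipsnap1 at 2.62, Rsl1d1 at 2.16, Plk2 at 2.02, Tmf1 at 1.98 and Tti2 at 1.95. Fam185a at 1.94, Kat6b at 1.92, Dnajc7 at 1.89, Cdh2 at 1.85 and Gnas at 1.83 followed. Plk2 is an activity-induced kinase gene, Cdh2 encodes N-cadherin and Gnas a G protein subunit. The largest differences toward sample 1 were in Insm2 at -3.21, Cyp2t4 at -2.61, 1700003D09Rik at -2.28, Iqsec1 at -2.09 and Olfr412 at -2.05. Nup43 at -2.04, 4930439D14Rik at -1.91, Scarf2 at -1.82, Gm8565 at -1.75 and Ucn at -1.75 followed. Of all these genes, only Cdh2, Gnas, 4930439D14Rik, Scarf2 and Gm8565 lay above the control-gene level in both samples. The others lay under it in 1 sample, so their differences rest on a value near background. Nipsnap1 had an intensity of 43.6 in sample 1 and 364 in sample 2, and Cyp2t4 of 250 and 55.6. With the brightest cluster per gene, Insm2 was at -0.86, under 2-fold, and the sign turned for Tti2, at -0.37, and Iqsec1, at 0.20. With a pseudocount of 16, Tti2 was at 0.85. Of the 2-fold differences, 273 were in the highest tertile of signal and 38 in the brightest 10%. The split depended on centring. Sample 2 held 54.5% of the 2-fold differences as given, 94.3% with no centring, and 82.2% when centred on genes above the control-gene level. Among genes at or above the median signal the share was 39.4%. No difference of a single gene had a replicate to set it against.

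Immediate early genes were higher in sample 2 in 12 of 16 cases, with a median difference of 0.85, above all 10000 random lists matched on signal. Among members above the control-gene level, Jun differed by 1.06, Arc by 1.02, Dusp6 by 0.56 and Egr3 by -0.85. Several neuronal lists were also higher in sample 2 than matched lists. Members higher in sample 2 were 9 of 14 pan-neuronal, 12 of 24 synaptic vesicle and 18 of 36 FMRP-bound genes. For channel, cerebellar and striatal genes they were 14 of 23, 6 of 11 and 4 of 7. The pan-neuronal median was 0.15 against -0.25 for matched lists (percentile 99.88), and its members above the control-gene level with the largest differences were Rbfox3 at 1.14, Nefm at 0.71, Stmn2 at -0.71 and Gap43 at -0.64. Synaptic vesicle genes had a median of 0.01 against -0.27 (percentile 99.71), with Stx1a at 0.82, Vamp2 at -0.78, Bsn at 0.76 and Nsf at 0.76. FMRP-bound mRNAs had 0.05 against -0.21 (percentile 99.5), with Arc at 1.02, Dync1h1 at 0.93, Nlgn2 at -0.92 and Herc1 at 0.86. Channel genes had 0.10 against -0.21 (percentile 98.9), with Cacnb4 at 0.77, Cacna1c at 0.76, Scn2a at 0.57 and Cacna1b at 0.51. Cerebellar genes had 0.04 (percentile 98.3), with Car8 at -0.71, Pvalb at -0.59, Pcp2 at -0.53 and Zic1 at 0.23, and striatal genes 0.13 (percentile 97.6), with Drd2 at -0.79, Ppp1r1b at -0.72, Penk at -0.66 and Tac1 at 0.38. The sign of a median depends on centring, which leaves the percentiles as they are. The median of the brightest 10% of genes was -0.29 as given, -0.08 centred on genes above the control-gene level and 0.15 with no centring. With these 2 settings the pan-neuronal median was 0.37 and 0.59, that of synaptic vesicle genes 0.23 and 0.46, of FMRP-bound mRNAs 0.26 and 0.49, and of immediate early genes 1.06 and 1.29. Genes with long mRNAs, a list made after the data were examined, moved the same way as the neuronal, channel and FMRP-bound lists, at percentile 99.98 of matched lists. Without matching on signal, the neuronal, synaptic, channel and FMRP-bound lists named here lay within the middle 95% of random lists, and the immediate early list did not. The striatal list also fell to percentile 97.1 under quantile normalization.

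Toward sample 1 relative to matched lists, cytosolic ribosomal protein genes had a median difference of -0.35 against 0.01 for matched lists (percentile 0.40), with 13 of 48 higher in sample 2. Members above the control-gene level included Rpl35a at -0.78, Fau at -0.75, Rpl12 at -0.75 and Rplp0 at -0.69. Replication-dependent histone genes had -0.57 against -0.01 (percentile 0.33), with H2bc18 at -0.97, H1f1 at -0.93, H4c14 at -0.87 and H1f5 at -0.54. The ribosomal protein median was -0.13 when centred on genes above the control-gene level and turned to 0.10, with 29 of 48 higher in sample 2, with no centring. Histone genes had -0.35 and -0.12. Genes with short mRNAs, another list made after the data were examined, moved the same way as both lists, at percentile 1.38. Pituitary genes, none above the control-gene level in both samples, had -0.79 (percentile 0.43), and the chemosensory receptor genes had -0.26, below all 10000 matched lists, though -0.04 and 0.19 under the other centrings. Of 37 lists of genes drawn at random, 1.85 would be expected outside the middle 95%, a number that need not hold for lists of related genes. In all, 37 lists were set against random lists, and 7 lay above the middle 95% and 4 below it. Among the 26 others, excitatory neuron genes lay at percentile 73.9, inhibitory neuron genes at 12.2, astrocyte genes at 89.5, myelin genes at 86.7, microglial genes at 59.1, postsynaptic density genes at 96.8 and oxidative phosphorylation genes at 5.62. Among genes at or above the median signal, the ribosomal protein list lay at percentile 21.6 and the histone list at 5.68, both inside the middle 95%. The lists share genes, so these counts are not independent, and the percentiles describe these 2 samples only.

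**Figure D3:**
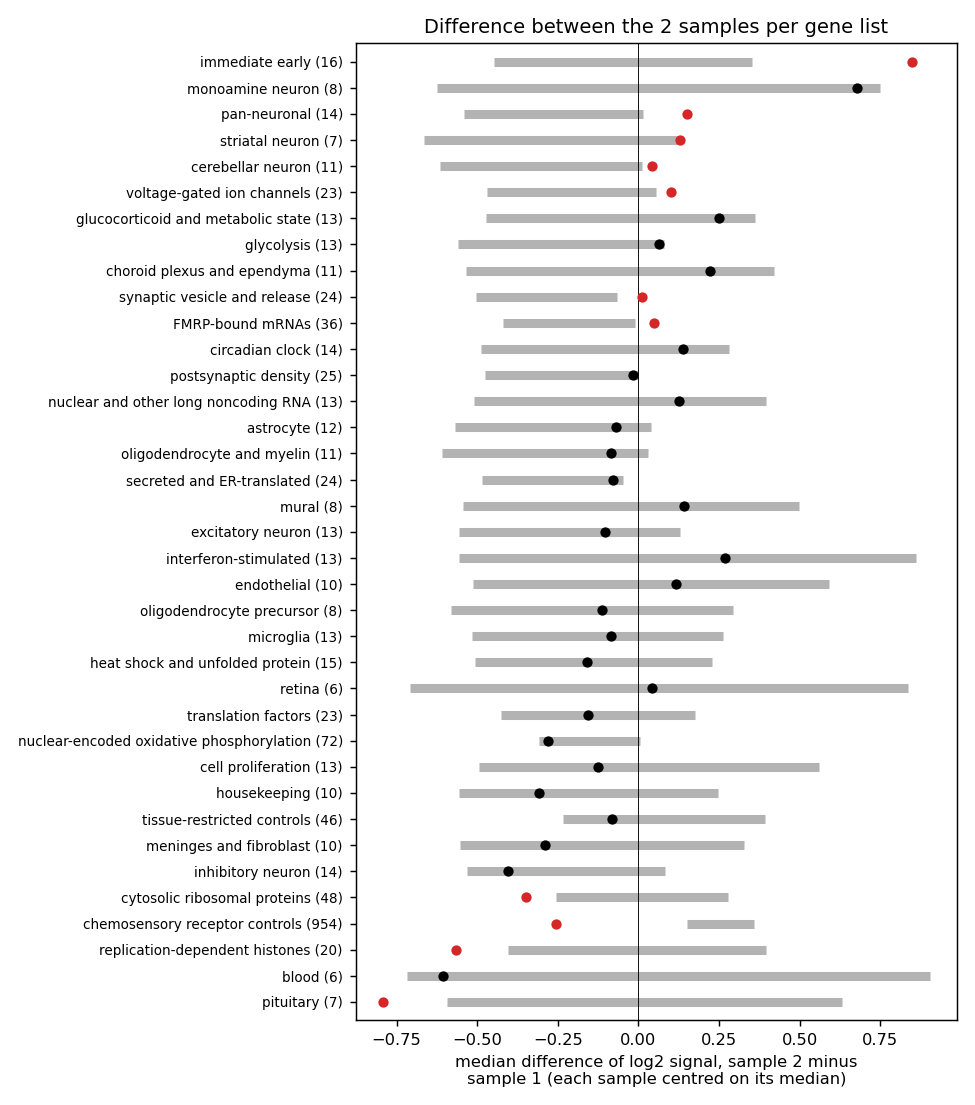
Median log2 difference of each gene list, sample 2 minus sample 1 after centring (x axis), as points, red outside and black inside the grey bars, which span the middle 95% of 10000 random lists matched on signal. The immediate early list, at 0.85, lies to the right of its bar and the cytosolic ribosomal protein list, at -0.35 (0.10 with no centring), to the left.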

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

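The split of unnamed clusters by identifier and the count among the brightest 100 were chosen only after the values had been seen. Signal above the control-gene level also appeared in parts of the table that the comparisons did not use. Among 76773 clusters with no gene symbol, 8805 (11.5%) lay above that level in both samples. Of the 100 brightest clusters, 62 had no symbol. The 6586 unnamed clusters whose identifiers lie under the lowest named one held 1683 above the level (25.6%), against 10.1% of the other unnamed clusters.

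Among clusters with several gene symbols, 385 (26.3%) lay above the control-gene level in both samples. One shared by Tuba1a, Tuba1c and Gm5620, named after its value was seen, was at 7153 ± 1080.3 (SD, n = 2). No explanation was tested for these signals.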

How the results depend on the processing

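Centring the differences otherwise or not at all was chosen only after the data were seen, and the other alternatives were planned. Signal over background limits the results, since the SD of the log2 difference was 2.95 in the lowest tertile of signal. No paired analysis was possible because the series has 1 group. Spearman's rho moved by less than 0.05 under each alternative run, and list levels kept within 1.5 times under quantile normalization, the brightest cluster per gene and a pseudocount of 16. With the brightest cluster per gene, 12 of 13 excitatory neuron, 11 of 12 astrocyte and 11 of 13 glycolysis genes lay above the level. FMRP-bound mRNAs were then at 31 of 36 and heat shock genes at 10 of 15. Genes named as dim that had over 1 cluster included Map2, Cux2, Glul, Ldha and Hsp90aa1. Pearson's r was 0.93 with the pseudocount and 0.90 for genes at or above the median signal. Genes above the control-gene level were 4675 with tissue-restricted controls, 5016 with the 99th percentile, and 8427 to 10666 in 1 sample alone. Genes 2-fold higher in sample 2 and in sample 1 were 385 and 288 with the pseudocount, 278 and 190 with tissue-restricted controls, 228 and 212 with the 99th percentile, 253 and 389 at or above the median signal, 1591 and 2191 at 1.5-fold, 1713 and 104 with no centring and 962 and 208 centred on genes above the level. Sample 2 then held 39.4% at or above the median signal and 42.1% at 1.5-fold. Centring cannot change the percentile of a list, but it shifts every median and turned that of cytosolic ribosomal proteins to 0.10 and of chemosensory receptor controls to 0.19 with no centring. Medians of several other lists turned too, among them oxidative phosphorylation, to 0.16, and inhibitory neuron, to 0.04.

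List members above the level became, with tissue-restricted controls, monoamine neuron 1, endothelial 1, mural 0, choroid plexus and ependyma 2, tissue-restricted controls 3, chemosensory receptor controls 7, translation factors 9, immediate early 3, circadian clock 4, glucocorticoid and metabolic state 3 and cell proliferation 0. With the 99th percentile they became monoamine neuron 1, endothelial 1, mural 0, choroid plexus and ependyma 2, tissue-restricted controls 2, chemosensory receptor controls 7, translation factors 9, immediate early 3, circadian clock 4, glucocorticoid and metabolic state 3 and cell proliferation 0. Counting clusters with several symbols gave pituitary 2 of 7, blood 2 of 8, cytosolic ribosomal proteins 27 of 78 and replication-dependent histones 20 of 62. In either sample alone the ranges were oligodendrocyte precursor 5 to 8, mural 3 to 6, choroid plexus and ependyma 4 to 7, pituitary 1 to 3, retina 0 to 3, blood 0 to 1, tissue-restricted controls 9 to 13, cytosolic ribosomal proteins 13 to 21, immediate early 6 to 11, glucocorticoid and metabolic state 6 to 10, interferon-stimulated 1 to 1 and sex-linked check 0 to 2. In each the higher count was in sample 2 alone, except pituitary, higher in sample 1 alone, and interferon-stimulated, at 1 in each. List difference percentiles that crossed a bound of the middle 95% were, without matching on signal, pan-neuronal 78.8, cerebellar neuron 62.4, striatal neuron 69.0, monoamine neuron 98.7, nuclear-encoded oxidative phosphorylation 1.04, synaptic vesicle and release 61.5, voltage-gated ion channels 77.0 and FMRP-bound mRNAs 72.4. Among genes at or above the median signal, where lists with under 5 members gave no value, they were cytosolic ribosomal proteins 21.6, nuclear-encoded oxidative phosphorylation 0.89, glycolysis 99.4, postsynaptic density 99.4, secreted and ER-translated 97.7 and replication-dependent histones 5.68. With the brightest cluster per gene they were striatal neuron 97.47, nuclear-encoded oxidative phosphorylation 1.28 and postsynaptic density 98.2, with quantile normalization striatal neuron 97.1 and postsynaptic density 98.7, and with the pseudocount postsynaptic density 97.8. With the brightest cluster per gene the difference turned to 0.20 for Iqsec1 and -0.37 for Tti2, and that of Insm2 was -0.86, while with the pseudocount that of Tti2 was 0.85. The cause of these changes was not tested, except that stricter control levels count fewer genes by construction.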

Other observations

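The tests of immediate early genes at or above the median signal and of long mRNAs in the highest tertile were chosen only after the results they bear on had been seen; the gene sets used here were chosen after the data were examined and before their own values were looked at. Mitochondrial ribosomal protein genes lay above the control-gene level in 45 of 75 cases. A second list of activity-induced genes did in 16 of 29. Long-mRNA genes, such as giant ubiquitin ligases, cadherins and chromatin regulators, did in 25 of 41, and short-mRNA genes of mitochondrial ribosomes, proteasomes, splicing and mitochondrial import in 78 of 130.

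Cytosolic ribosomal protein genes had a median rank of 38.7 (95% bootstrap interval 29.7 to 50.3). The mitochondrial ribosomal protein genes, part of the short-mRNA list, were not dim as a family, with a median rank of 69.1 (59.0 to 74.6). Length was not measured, so this covers that family and not short mRNAs as such. A candidate explanation is that genes with processed pseudogene copies read dim on this array, as the 280 other genes with a named copy had a median rank of 42.4 (36.0 to 48.0). Of these 280, 104 lay above the control-gene level in both samples, against 41.3% of all genes. Ribosomal protein genes with a named copy had a median rank of 33.3 (23.1 to 50.9), with 10 of 36 above the level. Those without one had 45.8 (37.7 to 55.2), with 3 of 12 above it. The intervals overlap, so within the family a copy was not shown to matter. A low share of these mRNAs on polysomes stays open and was not tested, as total RNA was not analysed here.

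Immediate early genes were higher in sample 2. The 10 members at or above the median signal had a median difference of 0.55, at percentile 99.84 of matched lists, with 6 of them higher in sample 2. Nr4a1, Egr1, Ier2 and Fosb among them did not lie above the control-gene level in both samples. This cut therefore still held dim signals, and their scatter is not excluded as a cause. The short-mRNA list lay the other way, at percentile 1.38, and the long-mRNA list lay the same way, at percentile 99.98. The lengths of the immediate early mRNAs were not measured, so these lists do not decide whether a length-related difference contributed. A difference in recent neuronal activity or handling may contribute, but the second activity list, which shares Homer1 with the postsynaptic density list, had a median of 0.03 at percentile 77.47 and did not decide it. With 1 group the animals, their handling and the gradients cannot be told apart.

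Long and short mRNAs differed between the samples, a pattern first noticed in the channel, FMRP-bound and ribosomal protein lists and then tested on other genes, though length was not measured and the short list holds a few functional families, so function and length are mixed. Relative to the median gene, the long-mRNA genes had a difference of 0.31 (29 of 41 higher in sample 2), at percentile 99.98 of matched lists, and the short-mRNA genes -0.23, at percentile 1.38, which is consistent with a length-related difference between the preparations. Among the 24 long-mRNA genes in the highest tertile the percentile was 99.98, with a median of 0.22 (16 higher in sample 2). This does not exclude a higher signal over background in sample 2. The tertile starts at a mean signal of 169, not far above the control-gene levels of 104 and 96.5. That level sat at percentile 57.0 of genes in sample 1 and 45.6 in sample 2. Under quantile normalization the long list lay at percentile 100, which does not bear on scaling, since the list moved by 0.02 and its matched lists by 0.03. The scaling of the arrays, RNA integrity, the fractions pooled, GC content, gene function and the animals stay open, and no biological explanation was tested, since the design has 1 group.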
